A study of Mus musculus with 6 samples.

How the data were processed

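Liver RNA of 6 male mice was sequenced, and the labels place 3 libraries in a normal group and 3 in a group given 20% carbon tetrachloride (CCl4) for 10 weeks to produce liver fibrosis. CCl4 is a solvent that liver enzymes convert to toxic radicals. The design also names another group that received CCl4 and the flavonoid didymin, and that group was not analysed here. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext kit. The submitters' processing notes name DESeq2, with no version, and the mouse genome build mm9. The aligner, the read counter and the annotation are not given in the sources used here.

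The deposited data were one table with a row per gene symbol. Per the file headers, the authors compared one set of 3 libraries, called ly_A (set A in the text), with another set of 3, called ly_B (set B). Neither name matches a title, description or other label of a sample. The labels therefore do not say which group either set belongs to, or that the sets are the normal and the CCl4 group. No group was inferred from the order of the columns or from the expression values. For this reason 18 columns of single libraries (normalised values, read counts and FPKM) were not used in any calculation. Only the 3 columns of the authors' own comparison were used. The totals per library were not used either, so the depth behind each gene was not examined. No standard deviation, standard error or interval across libraries is given, because columns that match no labelled sample were left out by choice.

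The log2 fold change in the authors' deposited table is taken as set A over set B, the order in which the comparison is named. When the table was opened and read by eye, a positive value in its first lines went with higher values in the columns of set A, which bears only on the sign. The p-value and the adjusted p-value of each gene are the authors' values as deposited. An adjusted p of exactly 1 stood in 2312 of 16426 rows. In the other 14114 rows the deposited adjusted p equalled a Benjamini-Hochberg adjustment of the deposited p over those rows alone, to within a relative difference of 9.47e-13. The 2312 rows were therefore treated as not tested, and the 14114 genes form the background of every test. Among the 2312 rows, 43 had a log2 fold change with a size above 10, up to 27.96. Fitted values of that size are not folds between measured levels, and large values of tested genes can also come from a set with almost no reads.

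A gene was called at an adjusted p under 0.05. Before the data were examined, 44 gene lists for liver, fibrosis, stress, immune and other cell types were fixed, with the rule for the genes named in the text. That plan allowed for columns that could not be tied to a group and then described the authors' comparison only. The 44 lists hold 1092 symbols, and 39 genes stand in more than 1 list. For each list the members called higher in either set were counted, over all genes tested and with the p adjusted over the list alone. The counts adjusted over the list alone are given where they differ from the first counts. Each of the 42 lists with at least 5 tested members was compared with all other tested genes by a two-sided Fisher's exact test per direction. Its p was adjusted by Benjamini-Hochberg over the 42 lists of that direction. This test was added after the data were seen. It treats genes as independent, and the correlation between genes was not estimated, so its p-values are too small by an unknown amount.

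The named genes are 10 fixed by name, the 8 protein-coding genes with the largest difference in each direction, and the 3 called members of each list with the largest difference. Where fewer than 2 members of a list passed, the 2 with the smallest p were added. Some genes that this rule takes are not reported here, and none was put in their place. The limits planned on mean expression and on overlap between libraries were not applied, since the library columns were left out. Protein-coding genes were found by symbol in GENCODE M21, which holds 16385 of the 16426 symbols (99.8%). That annotation belongs to another genome build than mm9, so no coordinates are given. It served only for gene type, transcript length and GC content. Families of near-identical genes, such as Mup, Cyp2c, Cyp3a, Gsta and Gbp genes, can share reads, and their single values are uncertain.

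The alternatives were an adjusted p under 0.01, a 2-fold difference as well, an adjustment over all 16426 rows, and 10000 random lists of the same size. Against random lists, a list was called when its median log2 fold change lay outside the central 95% of theirs. Unlike the p of Fisher's exact test, this call was not adjusted over the lists, so some of these calls can arise by chance. The random lists were matched on size only, and they too treat genes as independent. A call against random lists alone is therefore weaker than a call by Fisher's exact test. In a simulated comparison the 14114 genes were drawn independently, and 2500 were shifted in each direction by 6 standard deviations. All 2500 of each were recovered. A seeded list of 30 with 25 shifted genes gave a Fisher p of 1.78e-14. Of 100 lists drawn at random from all simulated genes, shifted or not, 6 gave a Fisher p under 0.05 in either direction. So large a shift made recovery near certain, so the simulation checks the code only. It does not bear on lists of correlated genes. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.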

Results

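Bulk RNA sequencing was done on liver of 6 male C57/BL mice, 3 in a normal group given saline and 3 in a group given 20% CCl4 for 10 weeks. The design asks which liver transcripts differ between normal and fibrotic liver. The authors' deposited table compares set A with set B, each of 3 libraries, without naming the group of either set. That the sets are the normal and the CCl4 group is not stated. All differences are therefore stated between set A and set B, and none is stated as an effect of CCl4.

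In the authors' deposited table, 15 of 26 markers of hepatocytes around the central vein and 23 of 28 male-biased liver genes were higher in set A, and 27 of 29 genes of the unfolded protein response were higher in set B. Glul, the glutamine synthetase of pericentral hepatocytes, was 33.3-fold higher in set A and had the smallest adjusted p of the authors' deposited table (log2 5.06, adjusted p = 4.36e-180). Timp1, an inhibitor of matrix proteases, was 24.9-fold higher in set B in the authors' deposited table (log2 -4.64, adjusted p = 1.41e-10). Of 14114 genes tested, 2554 were higher in set A and 2499 were higher in set B in the authors' deposited table, together 35.8%. A difference of at least 2-fold was reached by 1542 genes higher in set A and 1108 higher in set B in the authors' deposited table. The median log2 fold change of the tested genes in the authors' deposited table was 0.07.

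Among called protein-coding genes, the 8 largest differences towards set B in the authors' deposited table belonged to Sprr1a (-13.05), Npy (-9.08), Sprr1b (-8.26), Atp13a4 (-8.09), Slc7a11 (-7.91), Areg (-7.56), Vmn2r3 (-7.26) and Gm3776 (-6.94). Sprr1a and Sprr1b encode small proline-rich proteins of squamous epithelium, Areg encodes the growth factor amphiregulin, and Slc7a11 encodes the cystine transporter. The 8 largest towards set A among called protein-coding genes in the authors' deposited table belonged to Cyp2c69 (11.91), Cyp2c40 (10.34), Mup11 (10.33), Slc1a2 (8.27), Mup18 (7.90), Hsd3b5 (7.81), Elovl3 (7.47) and Mup19 (7.42). Slc1a2 is a glutamate transporter of pericentral hepatocytes, and Mup genes encode major urinary proteins. The largest adjusted p among these 16 genes in the authors' deposited table was 1.63e-05 (Hsd3b5). These log2 values are fitted values. How many reads lie behind the lower set was not examined, since the library columns were left out by choice. The ranking therefore has no floor on expression. Single values of Cyp2c and Mup genes, and of other families of near-identical genes named below such as Gsta, Saa, Oas and Hba genes, are uncertain, since copies can share reads.

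Of the 42 lists tested, 15 held more genes higher in set A, and 5 more genes higher in set B, than the other genes did (two-sided Fisher's exact test, adjusted p under 0.05). The 5 were the unfolded protein response, matrix proteases and inhibitors, the TGF-beta pathway, NRF2 targets and immediate early genes. The share of all tested genes was 18.1% for calls higher in set A and 17.7% for calls higher in set B, counted from the authors' deposited table.

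**Figure D1:**
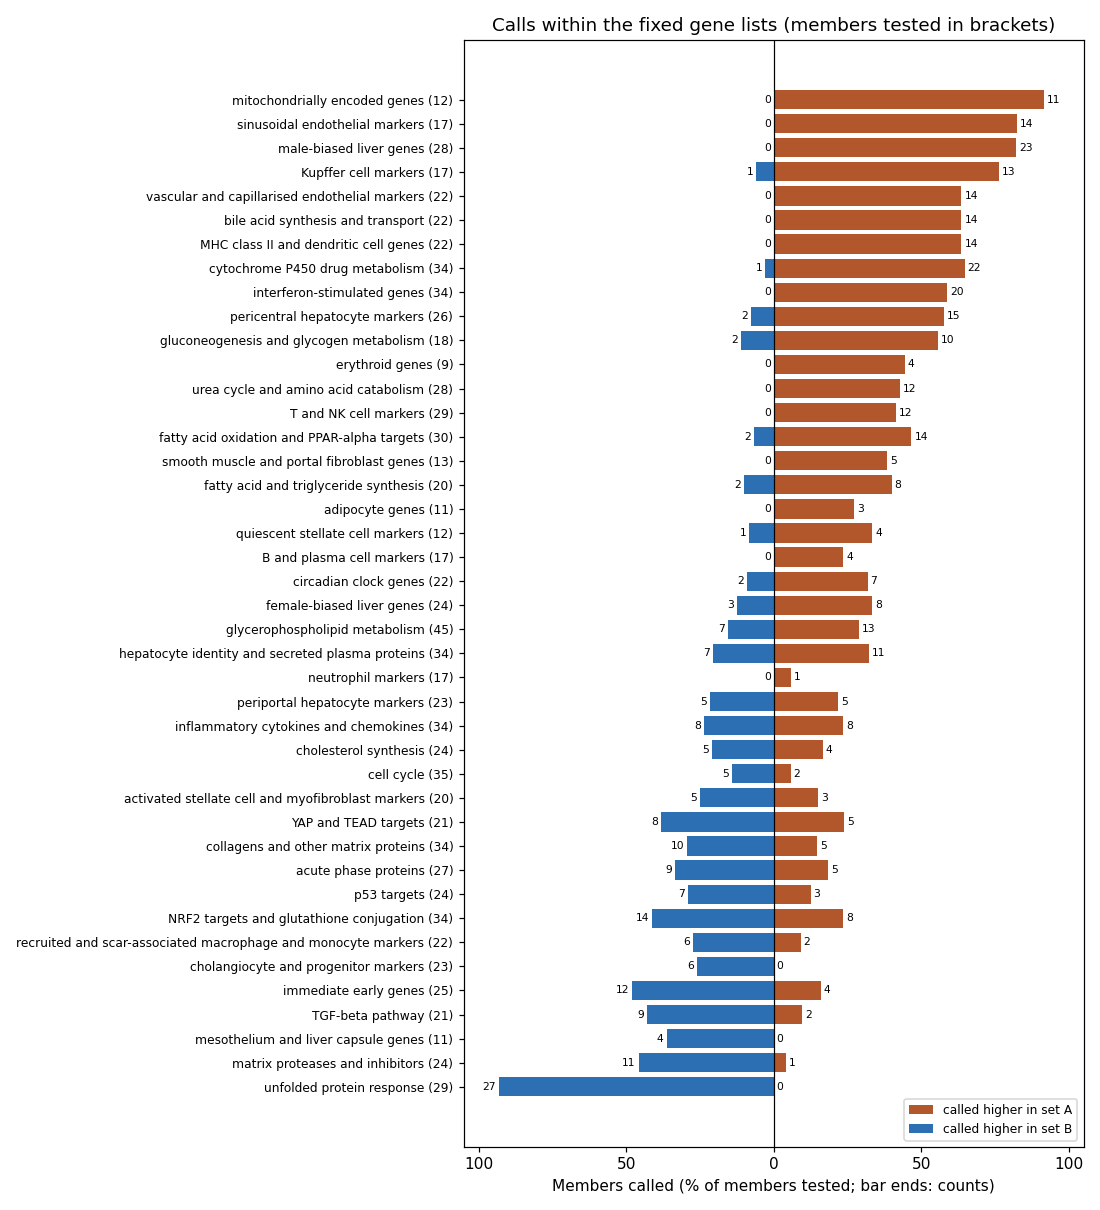
Members of each of 42 fixed gene lists called higher in set A (bars to the right) or in set B (bars to the left), as a percent of the members tested, with counts at the bar ends and the number tested in brackets. The unfolded protein response stands at one end with 27 of 29 members higher in set B, and the mitochondrially encoded genes at the other with 11 of 12 higher in set A.

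Extracellular matrix genes differed in both directions, while 11 of the 12 called matrix proteases and inhibitors were higher in set B in the authors' deposited table. Of 34 collagens and other matrix proteins, 5 were higher in set A and 10 in set B in the authors' deposited table (5 and 12 adjusted over the list alone). Nid1, a basement membrane protein, was higher in set B by a log2 value of -3.51, Vcan, a proteoglycan, was higher in set B at -3.06, and Col5a3 was higher in set A at 3.06 in the authors' deposited table (largest adjusted p = 0.000541). The list's share of calls did not differ from that of other genes by Fisher's exact test (adjusted p = 0.91 for set A and 0.24 for set B). Its median lay towards set B beyond random lists. Calls against random lists, here and below, were not adjusted over the lists. Col1a1 and Col3a1, the fibrillar collagens of scar tissue, did not pass in the authors' deposited table, at -0.66 (adjusted p = 0.0859) and 0.15 (adjusted p = 0.778). Of 24 matrix proteases and inhibitors, 1 was higher in set A and 11 in set B in the authors' deposited table, more than among other genes (Fisher's exact test, adjusted p = 0.0142). Mmp12, the macrophage elastase, stood at -6.31 and the collagenase Mmp13 at -3.45 in the authors' deposited table (largest adjusted p = 4.57e-05). Of 11 tested genes of mesothelium and liver capsule, 4 were higher in set B and 0 in set A in the authors' deposited table, with Upk3b at -3.32, Msln at -3.25 and Upk1b at -3.08. That list did not differ from other genes by Fisher's exact test (adjusted p = 0.24 for set B), but it was called towards set B with a 2-fold difference as well and against random lists.

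Markers of activated stellate cells, the matrix-producing cells of the liver, were split. Of 20 tested, 3 were higher in set A and 5 in set B in the authors' deposited table (4 and 5 adjusted over the list alone). Besides Timp1, the largest differences among called members were Thy1 at 1.90 and Myl9 at 1.79, both higher in set A in the authors' deposited table (largest adjusted p = 0.00331). Acta2, the smooth muscle actin of myofibroblasts, did not pass in the authors' deposited table (log2 1.22, adjusted p = 0.327). Of 12 markers of quiescent stellate cells, 4 were higher in set A and 1 in set B in the authors' deposited table, with Ntm at 1.83, Ecm1 at 1.79 and Angptl6 at 1.66. Neither stellate cell list differed from other genes by Fisher's exact test (smallest adjusted p = 0.386). Of 21 genes of the TGF-beta pathway, 2 were higher in set A and 9 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.0383). The ligand Tgfb2 at -2.73 and the receptor Tgfbr2 at -1.16 were higher in set B and the co-receptor Eng at 1.21 in set A in the authors' deposited table. Tgfb1 did not pass in the authors' deposited table (log2 0.37, adjusted p = 0.293). The call of the TGF-beta list ended when a 2-fold difference was also required. Of 21 YAP and TEAD targets, 5 were higher in set A and 8 in set B in the authors' deposited table, with Tgfb2 at -2.73, Ajuba at -2.67 and Nt5e at 1.89 (Fisher's exact test, adjusted p = 0.0685 for set B). Of 13 tested smooth muscle and portal fibroblast genes, 5 were higher in set A and 0 in set B in the authors' deposited table (7 and 0 adjusted over the list alone), with Clec3b at 2.83, Pln at 2.19 and Fbln1 at 1.53 (Fisher's exact test, adjusted p = 0.139). This list was called towards set A with a 2-fold difference as well and against random lists.

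Most cytochrome P450 genes of drug metabolism that passed were higher in set A. Of 34 tested, 22 were higher in set A and 1 in set B in the authors' deposited table (26 and 2 adjusted over the list alone; Fisher's exact test, adjusted p = 5.19e-08). Besides Cyp2c69 and Cyp2c40, Cyp2c38 was higher in set A at 5.14 in the authors' deposited table (adjusted p = 3.15e-57). Cyp2e1, the enzyme that activates CCl4, was 14.7-fold higher in set A in the authors' deposited table (log2 3.88, adjusted p = 9e-50). Of 34 tested NRF2 targets and glutathione conjugation genes, 8 were higher in set A and 14 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.0142 for set B). Slc7a11 at -7.91, the glutathione transferase Gsta1 at -6.91 and sulfiredoxin, Srxn1, at -3.45 were the largest among called members in the authors' deposited table (largest adjusted p = 1.04e-17).

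Bile acid genes that passed were higher in set A. Of 22, 14 were higher in set A and 0 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 1.35e-05). Cyp8b1, the sterol 12-alpha-hydroxylase, was 98.7-fold higher in set A, the uptake transporter Slco1a1 24.3-fold and the oxysterol hydroxylase Cyp7b1 7.01-fold in the authors' deposited table (largest adjusted p = 1.62e-10). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 6.23-fold higher in set A in the authors' deposited table (adjusted p = 7.64e-05). Of 30 genes of fatty acid oxidation and PPAR-alpha targets, 14 were higher in set A and 2 in set B in the authors' deposited table (15 and 2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00117). The pyruvate dehydrogenase kinase Pdk4 stood at 2.57, Acot1 at 1.71 and Acaa1b at 1.55 in the authors' deposited table (largest adjusted p = 0.0114). Of 20 genes of fatty acid and triglyceride synthesis, 8 were higher in set A and 2 in set B in the authors' deposited table (8 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0449). Thrsp at 3.98, the transcription factor Mlxipl at 2.64 and Acss2 at 1.57 had the largest differences among called members in the authors' deposited table (largest adjusted p = 5.44e-11). The call of the oxidation list ended at an adjusted p under 0.01, and that of the synthesis list when a 2-fold difference was also required and against random lists.

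Genes of cholesterol synthesis and of glycerophospholipid metabolism were called in both directions. Of 24 cholesterol synthesis genes, 4 were higher in set A and 5 in set B in the authors' deposited table (4 and 3 at an adjusted p under 0.01), with Tm7sf2 at 1.54 and Mvd at -1.38. Of 45 tested glycerophospholipid genes, 13 were higher in set A and 7 in set B in the authors' deposited table (8 and 2 at an adjusted p under 0.01, 6 and 1 with a 2-fold difference as well). The phospholipase Pla2g16 at 3.18 and the phosphatidate phosphatase Lpin1 at 2.64 were higher in set A and the ethanolamine kinase Etnk1 at -1.76 in set B in the authors' deposited table (largest adjusted p = 0.000443). Neither list differed from other genes by Fisher's exact test (smallest adjusted p = 0.142).

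Most pericentral hepatocyte markers that passed were higher in set A, while periportal markers that passed were split. Of 26 pericentral markers, 15 were higher in set A and 2 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 3.02e-05). Slc1a2 at 8.27, Glul at 5.06 and the Wnt target Sp5 at 4.43 were the largest among called members in the authors' deposited table (largest adjusted p = 1.27e-05). Of 23 periportal markers, 5 were higher in set A and 5 in set B in the authors' deposited table, with Serpina1e at 2.73, the cadherin Cdh1 at -2.67 and Apoc2 at 1.63 (Fisher's exact test, smallest adjusted p = 0.685). The difference between these lists was not tested. Of 34 genes of hepatocyte identity and plasma proteins, 11 were higher in set A and 7 in set B in the authors' deposited table (12 and 7 adjusted over the list alone; Fisher's exact test, smallest adjusted p = 0.0982). Counted at an adjusted p under 0.01, this list held more genes higher in set A than other genes did. The transcription factor Onecut1 was higher in set B at -4.05, and the nuclear receptors Nr1i2 at 1.80 and Nr1i3 at 1.41 were higher in set A in the authors' deposited table (largest adjusted p = 0.000114). Alb, which encodes albumin, did not pass in the authors' deposited table (log2 0.19, adjusted p = 0.565).

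The lists of nitrogen and of glucose metabolism each held more genes higher in set A than other genes did, with members that did not pass in both. Of 28 tested genes of the urea cycle and amino acid catabolism, 12 were higher in set A and 0 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.00665), a call that ended when a 2-fold difference was also required. Bhmt, a methyltransferase of methionine metabolism, stood at 3.48, Asl at 1.74 and Hpd at 1.61 in the authors' deposited table (largest adjusted p = 2.63e-05). Of 18 genes of gluconeogenesis and glycogen, 10 were higher in set A and 2 in set B in the authors' deposited table (10 and 3 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00137). The glucose-6-phosphatase G6pc was 7.47-fold higher in set A and the transporter Slc37a4 3.44-fold in the authors' deposited table (largest adjusted p = 1.3e-05).

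Genes with male-biased expression in mouse liver were higher in set A where they passed, although every animal is labelled male. Of 28 tested, 23 were higher in set A and 0 in set B in the authors' deposited table (24 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 1.24e-11). Mup11 at 10.33, the steroid dehydrogenase Hsd3b5 at 7.81 and the fatty acid elongase Elovl3 at 7.47 had the largest differences among called members in the authors' deposited table. Of 24 tested female-biased genes, 8 were higher in set A and 3 in set B in the authors' deposited table (11 and 3 adjusted over the list alone; Fisher's exact test, smallest adjusted p = 0.131). The female-biased list was called towards set A with a 2-fold difference as well and against random lists. Cyp2c69 and Cyp2c40, which also stand in the cytochrome list, had the largest differences among the called members in the authors' deposited table.

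Genes of the unfolded protein response, which raises folding capacity in the endoplasmic reticulum, were higher in set B almost throughout. Of 29, 27 were higher in set B and 0 in set A in the authors' deposited table (Fisher's exact test, adjusted p = 5.24e-17). Hspa5, the chaperone BiP, was 5.05-fold higher in set B, Ddit3, the transcription factor CHOP, 5.23-fold, Sdf2l1 5.49-fold, Hyou1 5.39-fold and Atf3 7.69-fold in the authors' deposited table (largest adjusted p = 0.000934). Of 25 tested immediate early genes, which respond within minutes to growth factors and stress, 4 were higher in set A and 12 in set B in the authors' deposited table (4 and 13 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0103 for set B). Egr1 was higher in set B at -2.82 and Gadd45g in set A at 3.28 in the authors' deposited table. Of 24 p53 targets, 3 were higher in set A and 7 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.305 for set B). The death receptor Tnfrsf10b at -2.89, Eda2r at -2.76 and the RNA-binding protein Zmat3 at -1.77 had the largest differences among called members in the authors' deposited table. Of 35 tested cell cycle genes, 2 were higher in set A and 5 in set B in the authors' deposited table (Fisher's exact test, smallest adjusted p = 0.142). Cyclin D1, Ccnd1, was 21.2-fold higher in set B, and the thymidine kinase Tk1 at 2.76 and survivin, Birc5, at 2.67 were higher in set A in the authors' deposited table (largest adjusted p = 0.00381).

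**Figure D2:**
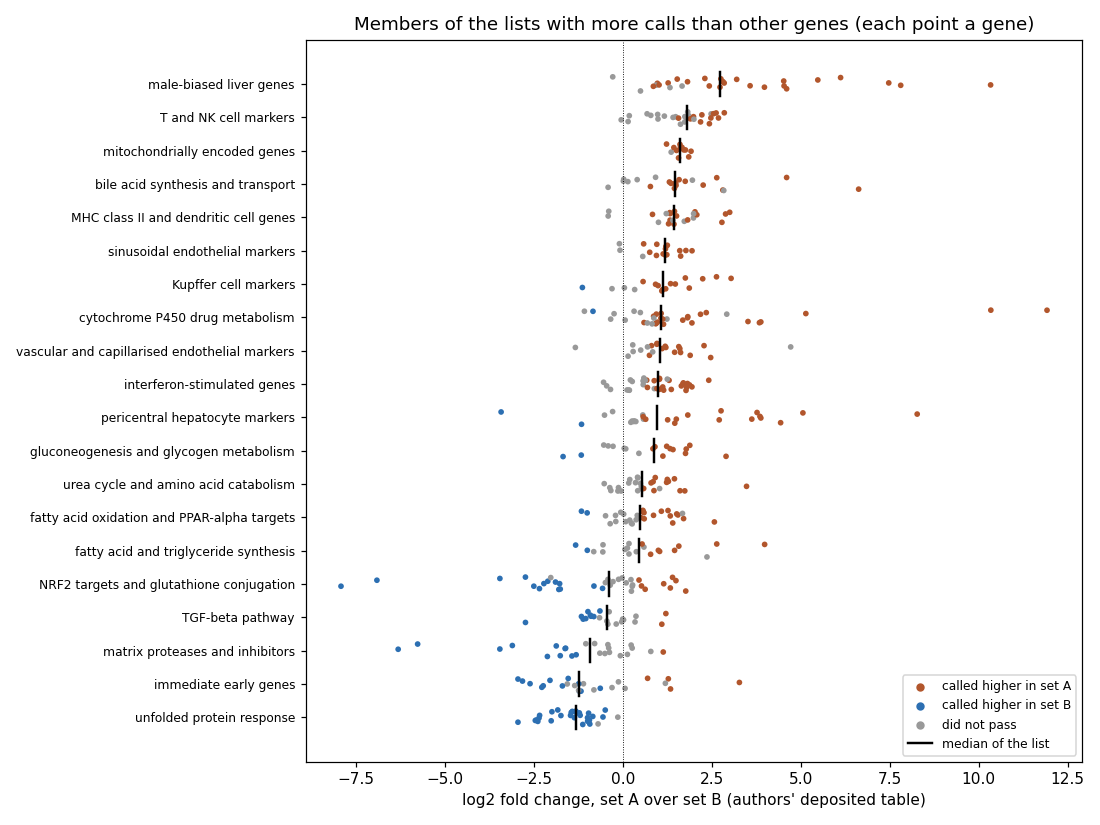
Log2 fold change of set A over set B (horizontal axis) for each tested member of the 20 lists that held more calls than other genes, one point per gene, coloured by its call, with the list's median as a black bar. The medians run from -1.32 for the unfolded protein response to 2.74 for male-biased liver genes.

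Markers of resident macrophages were mostly higher in set A, and several markers of recruited macrophages were higher in set B. The difference between these lists was not tested. Of 17 Kupffer cell markers, which mark resident liver macrophages, 13 were higher in set A and 1 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 1.74e-06). Timd4 at 3.04, Clec4f at 2.63 and Folr2 at 2.24 were the largest among called members in the authors' deposited table (largest adjusted p = 2.44e-06). Of 22 tested markers of recruited and scar-associated macrophages and monocytes, 2 were higher in set A and 6 in set B in the authors' deposited table (Fisher's exact test, smallest adjusted p = 0.419), and with a 2-fold difference as well that list was called towards set B. Gpnmb, a lysosomal glycoprotein, was 30.6-fold higher in set B, the chitinase-like Chil3 27.5-fold and galectin 3, Lgals3, 6.98-fold in the authors' deposited table (largest adjusted p = 2.24e-11). Of 17 tested neutrophil markers, 1 was higher in set A and 0 in set B in the authors' deposited table, Fpr1 at 1.45 (adjusted p = 0.00361), and Clec4d stood at -1.52 (adjusted p = 0.105). The neutrophil list did not differ from other genes by Fisher's exact test (smallest adjusted p = 0.132).

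Lymphocyte, antigen presentation and interferon genes were higher in set A where they passed. Of 29 tested T and NK cell markers, 12 were higher in set A and 0 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.00882), a call that ended at an adjusted p under 0.01. The cytotoxic granule genes Prf1 at 2.85, Gzmb at 2.69 and Gzma at 2.62 had the largest differences among called members in the authors' deposited table (largest adjusted p = 0.0084). Of 17 tested B and plasma cell markers, 4 were higher in set A and 0 in set B in the authors' deposited table (2 and 0 adjusted over the list alone), with Cd79a at 1.62 and Cd79b at 1.47 (Fisher's exact test, adjusted p = 0.655 for set A), and against random lists this list was called towards set A. Of 22 MHC class II and dendritic cell genes, 14 were higher in set A and 0 in set B in the authors' deposited table (16 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 1.35e-05), with Xcr1 8.02-fold, Cd209a 7.40-fold and Itgae 6.89-fold higher in set A. At an adjusted p under 0.01, 7 of these genes and 6 T and NK cell markers were higher in set A in the authors' deposited table. Of 34 interferon-stimulated genes, 20 were higher in set A and 0 in set B in the authors' deposited table (22 and 0 adjusted over the list alone; 13 higher in set A at an adjusted p under 0.01; Fisher's exact test, adjusted p = 1.13e-06). The immunoproteasome subunit Psmb9 at 2.41 and the antiviral genes Oas2 at 1.94 and Mx1 at 1.88 were the largest among called members in the authors' deposited table (largest adjusted p = 0.0103). Of 9 tested erythroid genes, 4 were higher in set A and 0 in set B in the authors' deposited table (5 and 0 adjusted over the list alone), with Hba-a1 at 1.97 and Hbb-bs at 1.56 (Fisher's exact test, smallest adjusted p = 0.131). The erythroid list was called towards set A with a 2-fold difference as well and against random lists.

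Cytokines and acute phase genes differed in both directions. Of 34 tested inflammatory cytokine and chemokine genes, 8 were higher in each set in the authors' deposited table (8 and 9 adjusted over the list alone; Fisher's exact test, smallest adjusted p = 0.499). With a 2-fold difference as well, the cytokine and the acute phase lists were called towards set B, the acute phase list also against random lists. The neutrophil chemoattractant Cxcl2 was 75.5-fold higher in set B, Cxcl14 8.67-fold higher in set B and the B cell chemokine Cxcl13 17.2-fold higher in set A in the authors' deposited table (largest adjusted p = 4.3e-06). Of 27 tested acute phase genes, 5 were higher in set A and 9 in set B in the authors' deposited table (6 and 11 adjusted over the list alone; Fisher's exact test, adjusted p = 0.119 for set B). The serum amyloid Saa2 at -2.82 and lipocalin 2, Lcn2, at -2.78 were higher in set B and the orosomucoid Orm3 at 4.03 in set A in the authors' deposited table (largest adjusted p = 0.0119).

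Endothelial markers that passed were higher in set A. Of 17 markers of sinusoidal endothelium, the fenestrated lining of the liver capillaries, 14 were higher in set A and 0 in set B in the authors' deposited table (15 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 2.15e-07). The Wnt enhancer Rspo3 at 1.94, the scavenger receptor Stab2 at 1.77 and Dnase1l3 at 1.63 had the largest differences among called members in the authors' deposited table (largest adjusted p = 0.000104). Of 22 vascular and capillarised endothelial markers, 14 were higher in set A and 0 in set B in the authors' deposited table (16 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 1.35e-05), with Cav1 at 2.47, Mmrn1 at 2.28 and Vwf at 1.89. Of 23 tested cholangiocyte and progenitor markers, 0 were higher in set A and 6 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.432 for set B), a list called towards set B with a 2-fold difference as well. The claudin Cldn4 at -2.95, the transcription factor Sox4 at -2.83 and the keratin Krt8 at -2.24 were the largest among called members in the authors' deposited table (largest adjusted p = 0.000465). For set A, that list held fewer calls than other genes (Fisher's exact test, adjusted p = 0.0377).

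Of 12 tested mitochondrially encoded genes, 11 were higher in set A and 0 in set B in the authors' deposited table (12 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 7.04e-07). The complex I gene mt-Nd4 was 3.78-fold higher, mt-Co2 3.61-fold and mt-Cytb 3.39-fold in the authors' deposited table (largest adjusted p = 0.00079). Of 22 circadian clock genes, 7 were higher in set A and 2 in set B in the authors' deposited table (8 and 2 adjusted over the list alone; Fisher's exact test, smallest adjusted p = 0.174), with Ciart at 2.67 and Usp2 at 2.65, and the list was called towards set A at an adjusted p under 0.01. Of 11 tested adipocyte genes, 3 were higher in set A and 0 in set B in the authors' deposited table (2 and 0 adjusted over the list alone), with Adrb3 at 4.72, Plin4 at 1.92 and Lipe at 1.30 (Fisher's exact test, smallest adjusted p = 0.388), and against random lists the list was called towards set A. Few genes of exocrine pancreas and skeletal muscle were tested, 3 and 1, and 16 more of skeletal muscle were listed without being tested. The elastase genes Cela2a at 2.59 and Cela1 at 0.98, and the muscle gene Neb at 3.30, were higher in set A in the authors' deposited table.

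These differences rest on the authors' p-values over 3 libraries per set, which measure the spread between these libraries only. The labels give no sequencing batch, and a difference in batch between the sets cannot be told apart from a difference in group.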

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

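The adjustment over all rows, Fisher's exact test and the random lists were chosen after the data were seen. At an adjusted p under 0.01 the counts stayed within 1.5 times of those reported, with 1736 genes higher in set A and 1790 in set B, as they did with an adjustment over all 16426 rows (2460 and 2404). Requiring a 2-fold difference as well left 1542 and 1108 genes. Lists with more genes higher in set A than other genes numbered 15 as reported and 15 at an adjusted p under 0.01, with 13 shared. With a 2-fold difference they numbered 16, with 13 shared, and by the median against random lists 19, with 14 shared. For set B, 5 lists were called as reported and the same 5 at an adjusted p under 0.01. With a 2-fold difference 9 were called, 4 of them shared, and against random lists 8, with 5 shared. For both sets, the numbers called against random lists were not adjusted over the lists. Of 88 list counts, 19 moved by over 1.5 times at an adjusted p under 0.01 and 21 with a 2-fold difference. None grew, as neither of these stricter settings can raise a count. At 0.01, the counts higher in set A became 3 for matrix proteins, 5 for NRF2 targets, 8 for fatty acid oxidation, 8 for glycerophospholipids, 3 for cytokines, 13 for interferon-stimulated genes and 0 for recruited macrophages. They became 6 for T and NK cells, 1 for B cells, 7 for MHC class II, 1 for erythroid genes, 0 for exocrine pancreas and 2 for smooth muscle. The counts higher in set B became 3 for cholesterol synthesis, 2 for glycerophospholipids, 5 for cytokines, 5 for YAP targets, 2 for mesothelium and 1 for clock genes. With a 2-fold difference, those higher in set A became 3 for matrix proteins, 5 for NRF2 targets, 8 for fatty acid oxidation, 5 for fatty acid synthesis, 6 for glycerophospholipids and 7 for the urea cycle. Periportal markers came to 3, hepatocyte identity to 6, acute phase to 3, recruited macrophages to 1, YAP targets to 3 and exocrine pancreas to 1. In set B, matrix proteins came to 6, TGF-beta to 4, cytochromes to 0, fatty acid synthesis to 1, glycerophospholipids to 1, periportal markers to 2, hepatocyte identity to 3, YAP targets to 4 and clock genes to 1. Of 136 genes that the rule for named genes takes and that passed, 20 did not pass at 0.01, and 1 differed by less than 2-fold (Cela1). Directions cannot turn under these settings, since the fold changes are the authors' own. No paired analysis was possible because the names of the library columns match no labelled sample, so a replicate number cannot be tied to a library. Since columns that match no labelled sample were left out by choice, other normalizations, low-count filters, tools and gene set tests, leaving out each library, a mean count of at least 10 and other splits of the samples were not run. Depth was not examined, so a gene that did not pass was not shown to be equal.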

Other observations

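The families described here, and the tests of shared reads, of the share of hepatocytes and of plasma cells, were chosen after the gene list results had been seen. Of 18 families defined by gene symbol, 17 had at least 5 tested members. Nuclear genes of the respiratory chain, whose products work beside the mitochondrially encoded subunits, were higher in set A in 58 of 76 cases and never higher in set B in the authors' deposited table (Fisher's exact test, adjusted p = 3.43e-27). Cox7a1, a muscle-type subunit of complex IV, stood at 3.86, Uqcr11 at 1.45 and Ndufb7 at 1.31 in the authors' deposited table. Of 80 cytosolic ribosomal protein genes, 25 were higher in set A and 3 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.0212), with Rpl36 at 1.16 and Rps18 at 1.12. Guanylate-binding proteins, interferon-induced GTPases, were higher in set A in 10 of 11 cases in the authors' deposited table (Fisher's exact test, adjusted p = 2.9e-06), with Gbp2b at 5.46 and Gbp11 at 3.37. Of 12 major urinary protein genes, 9 were higher in set A in the authors' deposited table (Fisher's exact test, adjusted p = 0.000151).

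Cytosolic tRNA synthetases, which charge tRNAs with amino acids, were higher in set B in 17 of 20 cases and never in set A in the authors' deposited table (Fisher's exact test, adjusted p = 1.77e-09), with Iars at -1.63 and Nars at -1.28. Of 12 tubulin genes, 8 were higher in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.00135), with Tubb2b at -3.05 and Tubb6 at -2.05. All 3 tested small proline-rich protein genes were higher in set B in the authors' deposited table, Sprr2b at -5.25 beside Sprr1a and Sprr1b, and no test was made of so few. Keratins were higher in set B in 3 of 9 cases in the authors' deposited table, with Krt5 at -5.77, and did not differ from other genes (Fisher's exact test, adjusted p = 0.432). A family of sarcomere and other striated muscle genes was set by symbol, and its rule can also take in non-muscle myosins and actinins. In it, 7 of 19 tested genes were higher in set A and 4 in set B in the authors' deposited table (Fisher's exact test, adjusted p = 0.122 for set A), with Lmod3 at 6.09, Csrp3 at 5.79 and Casq2 at 4.46. Of 37 tested proteasome subunits, 5 were higher in set A and 9 in set B in the authors' deposited table. This family did not differ from other genes (Fisher's exact test, smallest adjusted p = 0.437). Among those higher in set A were the immunoproteasome genes Psmb9 at 2.41, Psmb8 at 1.69 and Psmb10 at 1.44, and among those higher in set B was Psmd1 at -1.71. The remaining 8 families did not differ from other genes in either direction (smallest adjusted p = 0.119).

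No explanation by saline or CCl4 was tested for any pattern, since the labels tie neither set to a group. Most male-biased liver genes were higher in set A, with a median of 2.74. Animals of different sex in the sets would need Y-linked genes to differ by at least 3 on the log2 scale, and the median of the 4 tested Y-linked genes was 0.22, none of them called, while Xist was not among the tested genes. Reads shared between near-identical copies would concern the multigene families, yet 75% of members outside those families (9 of 12) were also higher in set A. A lower share of hepatocytes in set B would lower hepatocyte genes alike, and the hepatocyte list had a median of 0.28 (95% bootstrap interval over genes 0.01 to 0.69), below the 1.37 that was asked for. These 3 explanations are argued against as the whole cause, while a batch difference stays open. A lower share of hepatocytes as part of the cause also stays open. The hepatocyte list was called towards set A at an adjusted p under 0.01. It was not called as reported, with a 2-fold difference or against random lists. A lower share would also raise genes of other cell types in set B, and those lists went both ways. Medians towards set A included 1.12 for Kupffer cells, 1.19 for sinusoidal endothelium and 1.80 for T and NK cells. Medians towards set B included -0.29 for cholangiocytes, -0.34 for activated stellate cells and -2.44 for mesothelium.

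Most genes of the unfolded protein response were higher in set B, with a median of -1.32. A trend with transcript length or GC content left the median at -1.37 once removed (95% bootstrap interval over genes -1.77 to -1.11), so such a trend is argued against. Plasma cells, which are rich in these chaperones, would bring their own transcripts. The 3 tested plasma cell genes had a median of 0.54, towards set A, with Jchain at 0.44, and none of them was called. Tissue handling stays open, as 12 of 25 immediate early genes were also higher in set B, and it was not tested.

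Most mitochondrially encoded genes were higher in set A, with a median of 1.61. A candidate explanation is a higher content of mitochondria per cell in set A, which predicts that nuclear respiratory chain genes move along, and their median was 0.90 (95% bootstrap interval over 76 genes 0.76 to 1.04) against the 0.81 that was asked for. The prediction was met, but that interval reaches below 0.81. RNA levels in bulk tissue do not measure mitochondria per cell, so this hypothesis stays open. A trend with length or GC content cannot be told apart from this hypothesis. Removing the trend left the mitochondrially encoded genes at 0.85 (95% bootstrap interval over genes 0.36 to 1.06), with the interval above 0. Yet only 41.7% of them lay within the range of length and GC of the other genes, so the removal cannot decide. The trend was not removed from the nuclear genes.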
